A study of Mus musculus with 12 samples.

How the data were processed

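RNA of the descending aorta was hybridised to 12 Agilent 1-colour (Cy3) arrays, 6 from mice aged 6 months and 6 from mice aged 20 months, 1 array per mouse. Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 10.7.1.1 under the protocol GE1_107_Sep09 on design 028005, whose probe positions refer to the mouse genome build mm9. The deposited scanner files hold, for each of 62976 spots, an intensity value: the processed green signal, from which background had been subtracted with spatial and multiplicative detrending and which had not been scaled between arrays. A deposited value table of log2 values covers the same 12 arrays. Its steps are not stated. Each probe's median over the 12 arrays is 0 in it, the column means differ by at most 0.000606, and per array its values correlate at 0.898 to 0.985 across probes with the median-centred scanner values (probes are not independent replicates). The scanner files were used for all comparisons and the table of log2 values as an alternative.

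The processed signal was taken to log2, spots flagged as outliers were left out, the remaining spots of a probe were averaged, and each array's 75th percentile over gene probes was subtracted. All values below are therefore log2 signals relative to that percentile. Of 55681 gene probes, 55630 were kept and 51 were left out because every spot was flagged on an array. Probes were named by RefSeq accession through a gene table of assembly GRCm38.p6, used for names alone (26413 probes), by symbol where the accession was missing from it (4594), or by the array's own name (4210). A further 20464 probes carry no gene name. Probe positions printed below are those of the array files. A probe entered if it stood well above background on at least 6 of the 12 arrays, whichever these were, which left 27583 probes. For each gene the probe with the highest mean signal was used, which gave 16611 genes.

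The ages were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table version 1.17.8), with age as the only term. The error given for a change is the standard error of the moderated fit. A gene was called changed at an adjusted p (Benjamini-Hochberg) under 0.05 over the genes tested, and a count at 1.5-fold or more stands beside it. There were 30 gene lists and 15 cell type marker lists, 45 in all. The 44 lists with at least 5 measured members were compared with limma's camera at its preset correlation of 0.01, adjusted over these lists, and beside it with camera at an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. The spread between mice was compared as the median over genes of the log2 ratio of the sample variances, with a two-sided permutation test on 100 draws of the residuals.

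Named genes were chosen by a fixed rule. The rule takes, among called genes whose 6 values at 1 age all lie above the 6 at the other, the 12 with the largest rise and the 12 with the largest fall, leaving out names that are model numbers, accessions or clones. It adds up to 4 members with the smallest p from each list that passed camera and, in any case, from the renin-angiotensin, TGF-beta and glutathione lists, and 10 genes always given: Cdkn2a, Eln, Acta2, Myh11, Nos3, Col1a1, Col3a1, Ucp1, Adipoq and Ptprc. The rule named 88 genes, 1 of which is not reported here. The lists, the rule, the comparison of the ages with its tests and all alternatives but 2 were chosen before the data were examined, and the tests of explanations in the closing part were not.

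The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the value table, no filter on dim probes, a filter on all 12 arrays, the slide as a fixed and as a random block, each slide alone, the replicate number as a block, eBayes with trend and robust settings, array weights, every probe tested, the mean over a gene's probes, and each array left out in turn. The 2 chosen after seeing the data left out 3 arrays that were high in heart muscle or T cell markers, and the 2 arrays with the most probes above background. On simulated data of the same size with 200 of 16611 genes changed, the procedure recovered 61.2% of 1.5-fold changes, 91.0% of 2-fold changes and 98.5% of 3-fold changes, and 5.65% of its calls were false. It made 0 calls where nothing had been changed. The simulated noise was independent between genes and arrays, without correlated genes or slide differences, so these rates need not hold for the real arrays. With 6 arrays per age, their number limits the precision of every value.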

Results

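The data describe gene expression in the descending aorta of male C57BL/6 mice at 6 months and at 20 months of age, with 6 mice in each group and 1 array per mouse. Each array held 59305 spots with gene probes. Between 47.5% and 55.8% of the gene probes stood well above background on an array. The arrays lay on 3 slides with 2 arrays of each age on each slide, and the 4 arrays of slide 3 were scanned on a later day. All 6 arrays at 20 months lay in column 3 of their slide, whereas 5 arrays at 6 months lay in column 1 and the remaining array in column 4, so that an effect of column 3 and an effect of age cannot be told apart. Markers of heart muscle or of T and NK cells were high in 3 arrays, called the arrays with markers of other tissues below. The mean of the heart muscle markers lay 3.59 above the 12-array mean of the same genes (log2) in 20 months replicate 1 and 2.32 above it in 6 months replicate 1, and the T and NK cell markers lay 1.1 above it in 6 months replicate 4. Signals of fat genes were high at both ages and so not confined to these 3 arrays. Ucp1 averaged 7.74 at 6 months and 7.10 at 20 months and Adipoq 6.99 and 6.84, beside 6.87 and 6.84 for the smooth muscle gene Myh11. Signals of different probes are not strictly comparable. Whether fat contributed to single changed genes was not tested.

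The series asks which genes of the mouse vessel wall differ between adult and old animals. At 20 months 45 genes were higher and 9 lower than at 6 months, out of 16611 tested (limma). Of these, 35 rose and 6 fell by at least 1.5-fold, and 16 rose and 2 fell by at least 2-fold. The largest named rise was that of Csprs, a component of a repeated Sp100-related sequence, followed by Igfbp2, a secreted binding protein of insulin-like growth factors, Serinc2, of the serine incorporator family, Nfasc, an adhesion molecule of axons, and Ibsp, the bone sialoprotein of mineralised matrix. Among named genes whose values separated the ages completely, the largest fall was that of Igf2bp2, which encodes an RNA-binding protein of the Igf2 messenger RNA, followed by Itm2a and by Pon1, the paraoxonase carried on high density lipoprotein.

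Csprs stood at -1.92 ± 0.58 at 6 months and 0.35 ± 0.27 at 20 months (log2 signal, SD, n = 6 each), a rise of 2.27 ± 0.23 (SE, as for every change given with ±) or 4.81-fold. Its probe lies on unplaced sequence assigned to chromosome 8 (111572 to 111631, mm9). Igfbp2 (chromosome 1, 72898677 to 72898736) went from 1.92 ± 0.76 to 3.82 ± 0.47, a rise of 1.90 ± 0.33 or 3.73-fold. Serinc2 (chromosome 4, 129930742 to 129930801) went from -2.04 ± 0.40 to -0.18 ± 0.48, a rise of 3.64-fold. Nfasc (chromosome 1, 134466568 to 134466627) rose by 1.59 ± 0.13 or 3.0-fold from -0.36 ± 0.18, and Ibsp (chromosome 5, 104740413 to 104740472) by 1.51 ± 0.20 or 2.85-fold from -2.43 ± 0.47. The adjusted p was 0.00153 for Csprs, 0.0300 for Igfbp2, 0.00581 for Serinc2, 1.5e-04 for Nfasc and 0.00712 for Ibsp. Rises of 1.04 to 1.36 were found for Sphkap, which anchors protein kinase A (1.36 ± 0.23), Lbhd2 (1.33 ± 0.19, an older clone name on the array, above background on 4 of 6 arrays at 6 months), Adcy1, an adenylyl cyclase (1.27 ± 0.19), Cntn1, an axonal adhesion molecule (1.26 ± 0.23), Prune2 (1.18 ± 0.13), Cd163l1, a scavenger receptor (1.16 ± 0.21), and Hapln1, the link protein of aggregating proteoglycans (1.04 ± 0.15). Their adjusted p ran from 0.00322 for Prune2 to 0.0363 for Cntn1 and Cd163l1.

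Igf2bp2 (chromosome 16, 22059260 to 22059319) went from -2.13 ± 0.23 at 6 months to -3.14 ± 0.33 at 20 months and so fell by 1.01 on the log2 scale (SE 0.15, adjusted p = 0.0142), with its probe above background on 4 of 6 arrays at 20 months. Itm2a (X chromosome, 104592916 to 104592975) fell by 0.87 (SE 0.13) and Pon1 (chromosome 6, 5118166 to 5118225) fell by 0.83 (SE 0.15). Mpped2 fell by 0.58 (SE 0.10), and the kinase gene Hunk fell by 0.40 (SE 0.07). The adjusted p was 0.0142 for Itm2a, 0.0354 for Pon1, 0.0384 for Mpped2 and 0.0284 for Hunk. In all of these 17 genes the 6 values at 20 months lay on 1 side of the 6 values at 6 months. No further named fall met that condition (Samd5, picked after its values were seen, fell by 0.86, adjusted p = 0.0279, without it), while 25 further named rises and, among genes known by model or clone names, 7 rises and 3 falls did.

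**Figure D1:**
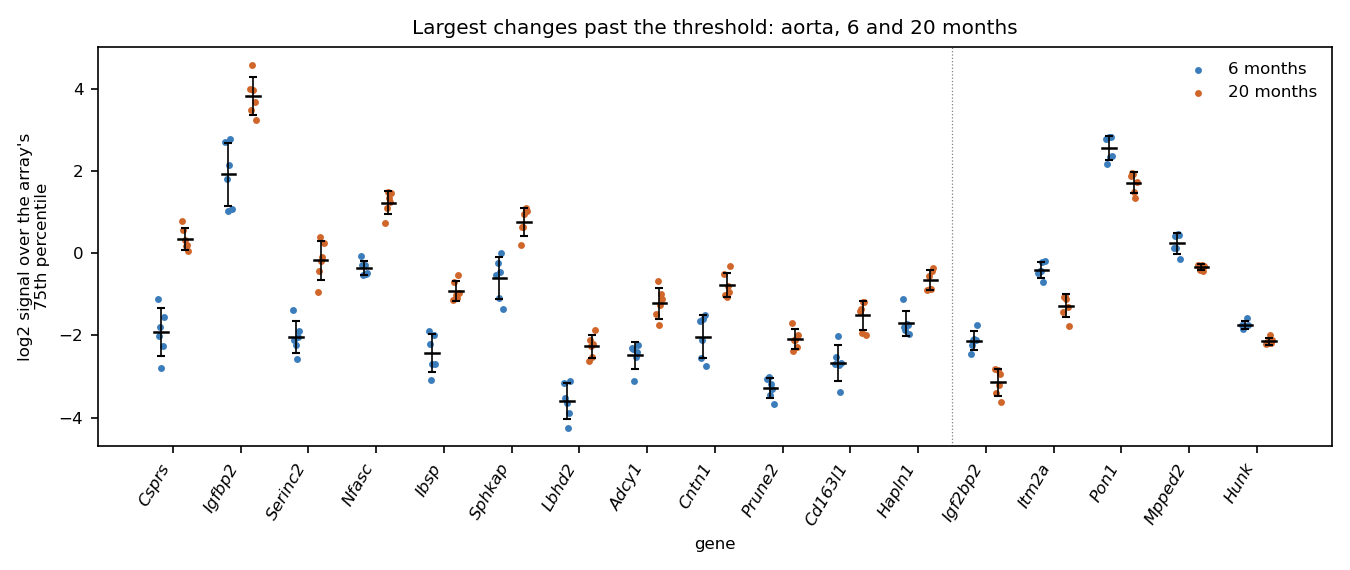
Log2 signal relative to the array's 75th percentile (vertical axis) of the 12 named genes with the largest rise and the 5 named genes that fell (horizontal axis), at 6 months and 20 months; points are mice (6 per age), horizontal bars are means and error bars SD. Csprs rose by 2.27 and Igfbp2 by 1.90, and Igf2bp2 fell by 1.01.

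Complete separation of the ages was found for 147 genes, where chance gives 0.216% of genes or about 36.0 over both directions. Of these 108 lay upwards and 39 downwards, where chance gives about 17.98 in each. The chance figures are averages. Genes move together, so a count by chance can lie far from them, and its spread was not computed. Complete separation held for 44 of the 45 higher and 8 of the 9 lower genes. All 54 changed genes had the same direction on each of the 3 slides. Csprs rose by 2.57, 2.63 and 1.60 on slides 1, 2 and 3, Igfbp2 by 2.32, 1.15 and 2.23, and Igf2bp2 fell by 0.94, 1.31 and 0.79. With the slide as a block 53 genes were higher and 13 lower. The count changed when 1 array was left out, which also lowers the sample size. It fell from 54 to 41, 39, 30, 30 and 31 without 6 months replicates 1, 2, 3, 4 and 5. Without 20 months replicates 2, 3, 4, 5 and 6 it fell to 23, 28, 24, 21 and 25. It rose to 63 without 6 months replicate 6 and to 59 without 20 months replicate 1. Without the 3 arrays with markers of other tissues 26 genes were higher and 4 lower. Csprs, Nfasc, Ibsp and Prune2 passed under all 27 alternatives that drew on all slides, whereas Igfbp2 and Cntn1 passed under 15, Sphkap under 14, Cd163l1 under 13, Pon1 under 12, Mpped2 under 11 and Hunk under 10, with adjusted p up to 0.141 for Igfbp2, 0.171 for Pon1 and 0.787 for Hunk. With normexp background correction, whose offset shrinks low signals, 12 of the 20 named genes past the threshold had changes smaller by more than 1.5 times. Among them were Csprs (1.44), Serinc2 (1.14), Ibsp (0.81), Prune2 (0.46) and Igf2bp2 (-0.35). Igf2bp2 then fell less than Itm2a (-0.57), Pon1 and Mpped2. Over the 27 alternatives the weakest fall of Pon1 was -0.76 and that of Mpped2 -0.48. The 3 probes of Csprs rose by 0.56 to 2.27, and with the mean over a gene's probes its rise was 1.31. In both settings Igfbp2 rose more than Csprs, by 1.83 and 1.88. With the mean over probes other genes did too, among them Serinc2 (its 3 probes by 1.66 to 1.86) and Nfasc (1 probe, 1.59). The call of Igfbp2 was lost without any 1 of 6 months replicates 2, 3 and 4 and 20 months replicates 1, 2, 3, 4 and 5.

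Several of the changed genes lay on 3 pieces of sequence, which were picked after their values were seen and are counted together here, although the position of the unplaced ones on the genome is not known. On chromosome 1 between 85 and 86 Mb and on the unplaced sequence assigned to chromosomes 1 and 8, 6 of 23 tested genes were changed, all of them higher, against 48 of 16588 elsewhere. These were Csprs, C130026I21Rik (2.42 ± 0.34), LOC100041081 (2.0 ± 0.27), LOC100041903 (1.90 ± 0.30), Gm2397 (0.90 ± 0.14) and LOC100041068. The probes of C130026I21Rik and LOC100041081 stood above background on 2 of 6 arrays each at 6 months, so that the sizes of their rises are uncertain. The probe of LOC100041068 stood above background on 0 of 6 arrays at 6 months and on 6 of 6 at 20 months, at least 2.61-fold higher. At the level of probes, named or not, 18 of the 53 on these pieces were higher and 0 lower, against 50 changed probes elsewhere. Of the 6 genes, C130026I21Rik and Gm2397 lay on chromosome 1, LOC100041081 and LOC100041903 on its unplaced sequence, and Csprs and LOC100041068 on that of chromosome 8. Sp100, Sp110 and Sp140, further along chromosome 1, changed by 0.01 ± 0.10, -0.07 ± 0.16 and 0.11 ± 0.10, none of which passed. Another probe of Sp140 rose by 0.55 ± 0.13 (adjusted p = 0.160 over all probes).

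**Figure D2:**
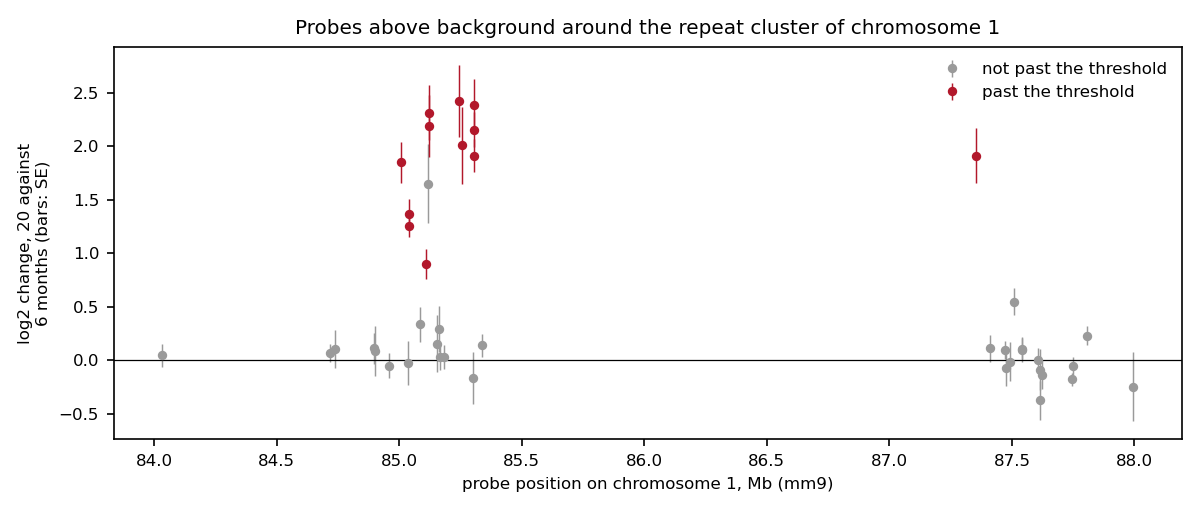
Log2 change at 20 months against 6 months (vertical axis, bars SE) of probes above background by their position on chromosome 1 in Mb (mm9, horizontal axis); red points passed an adjusted p of 0.05 over all probes and grey points did not. Of the 20 probes between 85 and 86 Mb, 11 were higher, and so was 1 probe outside it at 87351659.

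Cartilage and calcification genes rose as a list (median change 0.26 over 16 measured members, camera adjusted p = 3.1e-05, and adjusted p = 0.068 with an estimated correlation). Over all genes 1 member, Ibsp, rose and 15 did not pass, whereas adjusted over the list alone 4 rose and 1 fell. Besides Ibsp these were Fmod, a collagen-binding proteoglycan (0.95 ± 0.20), Comp, the cartilage oligomeric matrix protein (0.71 ± 0.16), and Mgp, an inhibitor of calcification (0.24 ± 0.07). Over all genes Comp passed under 3 alternatives, with array weights, without 6 months replicate 1 and without the 3 arrays with markers of other tissues (adjusted p from 0.0227 to 0.445 over the alternatives). Fmod passed under these 3, without 20 months replicate 1 and with the slide as a fixed or random block. The member lower over the list alone was the phosphatase gene Alpl (-0.34 ± 0.11). Senescence genes rose as a list (median 0.07 over 19 members, adjusted p = 0.017, and adjusted p = 0.179 with an estimated correlation). Of these members 11 had a positive and 8 a negative change, so the list did not move as 1. Igfbp4 alone passed over all genes, with a rise of 0.42 ± 0.08. Adjusted over the list alone 3 rose, namely Igfbp4, the cell cycle inhibitor Cdkn2a (0.70 ± 0.16) and the cyclin Ccnd1 (0.45 ± 0.12), and 1 fell, the histone methyltransferase Ezh2 (-0.60 ± 0.20). Over all genes the adjusted p of Cdkn2a was 0.117, and from 0.0235 (without 6 months replicate 3, the 1 alternative it passed under) to 0.539 with normexp, where its change was 0.19. The senescence call was lost with median scaling, with the filter on all 12 arrays and without 6 months replicate 6, with adjusted p up to 0.0872. Fry passed 2 lists, cartilage (adjusted p = 0.0118) and senescence (0.0374), both upwards.

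Macrophage markers rose as a list, all 23 measured members having a positive change (median 0.23, adjusted p = 8.5e-09, and adjusted p = 0.569 with an estimated correlation). That estimate was 0.52, so the 23 signs are not independent. The coagulation factor gene F13a1 rose (0.55 ± 0.10) and was the 1 member past the threshold both over all genes and adjusted over the list alone. The mannose receptor gene Mrc1 (0.42 ± 0.15), the Fc receptor gene Fcgr1 (0.49 ± 0.18) and the folate receptor gene Folr2 (0.29 ± 0.11) did not pass. Mast cell markers rose as a list (median 0.60 over 7 members, adjusted p = 1.4e-05, and adjusted p = 0.179 with an estimated correlation). The tryptase gene Tpsb2 rose over all genes (0.60 ± 0.11, adjusted p = 0.0416), and adjusted over the list alone 4 members rose, the others being the chymases Mcpt4 (0.62 ± 0.16) and Cma1 (0.66 ± 0.18) and the carboxypeptidase Cpa3 (0.69 ± 0.22). Without 6 months replicate 6, Cma1 (adjusted p = 0.025) and Mcpt4 passed over all genes too. Erythroid genes rose as a list (median 0.51 over 6 members, adjusted p = 0.00377, and adjusted p = 0.72 with an estimated correlation) and had 0 members past the threshold over all genes or adjusted over the list alone. The globin genes Hba-a1 (0.59 ± 0.28), Hbb-b2 (0.59 ± 0.31) and Hbb-bt (0.45 ± 0.29) and the haem synthesis gene Alas2 (0.57 ± 0.30) had positive changes. Tpsb2 passed under 9 and F13a1 and Igfbp4 under 12 of the 27 alternatives.

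Mesothelial markers fell as a list (median -1.74 over 6 members, adjusted p = 2.5e-06, and adjusted p = 0.179 with an estimated correlation). None passed over all genes and 5 fell adjusted over the list alone. The changes were -3.10 ± 0.78 for Msln, -2.67 ± 0.70 for Upk3b, -1.58 ± 0.44 for Krt19 and -1.90 ± 0.64 for Wt1. Their probes stood above background at 20 months on 4, 2, 4 and 2 of 6 arrays, so that the sizes rest on dim signals, and with normexp the changes were -1.84, -0.82, -0.74 and -0.41. The list mean differed widely between mice, from -1.77 in 20 months replicate 1 to 0.61 in 20 months replicate 5 and from -0.10 to 1.91 at 6 months. Brown adipocyte markers fell as a list (median -0.33 over 13 members, adjusted p = 0.00703, and adjusted p = 0.72 with an estimated correlation) and had 0 members past the threshold over all genes or adjusted over the list alone. Their examples were Otop1 (-0.68 ± 0.30), Cpt1b (-0.40 ± 0.18), Elovl3 (-1.37 ± 0.69) and Ucp1, the uncoupling protein of brown fat (-0.64 ± 0.31). The call was lost without 6 months replicate 6 (adjusted p = 0.0932) and without the 2 arrays with the most probes above background (0.0672).

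Oxidative phosphorylation genes fell as a list: 58 of 59 members had a negative change, with a median of -0.24 (adjusted p = 2.2e-10, and adjusted p = 0.72 with an estimated correlation). That estimate was 0.86, so the members moved together and their signs are not independent. Taken as 1 mean per array, the list changed by -0.24 (SE 0.15), which is not a clear fall. No member passed over all genes or adjusted over the list alone, and Cox6c (-0.31 ± 0.11), Atp5g2 (-0.24 ± 0.09), Atp5j (-0.17 ± 0.07) and Atp5e (-0.37 ± 0.15), subunits of cytochrome c oxidase and of ATP synthase, had the smallest p. The list's median was -0.03, -0.22 and -0.45 on slides 1, 2 and 3, beside -0.04, -0.29 and -0.68 for the brown adipocyte markers. Cell cycle genes fell as a list (median -0.13 over 34 members, adjusted p = 0.0496, and adjusted p = 0.72 with an estimated correlation). None passed over all genes or adjusted over the list alone: Mcm7 (-0.21 ± 0.08), Cdt1 (-0.31 ± 0.14) and Plk1 (-0.42 ± 0.21) had negative changes and Mcm6 a positive one (0.21 ± 0.12). The list mean was 0.77 in 6 months replicate 4, the array with high T and NK cell markers, and at most 0.06 in the others. The call held under 16 of 25 alternatives: it was lost with the slide as a block (adjusted p = 0.097), with the trend and robust settings, without 6 months replicate 4 or 20 months replicates 1, 2, 3 or 6 and without the 2 arrays with the most probes above background (up to 0.949 over the alternatives), and without the 3 arrays with markers of other tissues camera placed the list upwards (adjusted p = 0.447).

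**Figure D3:**
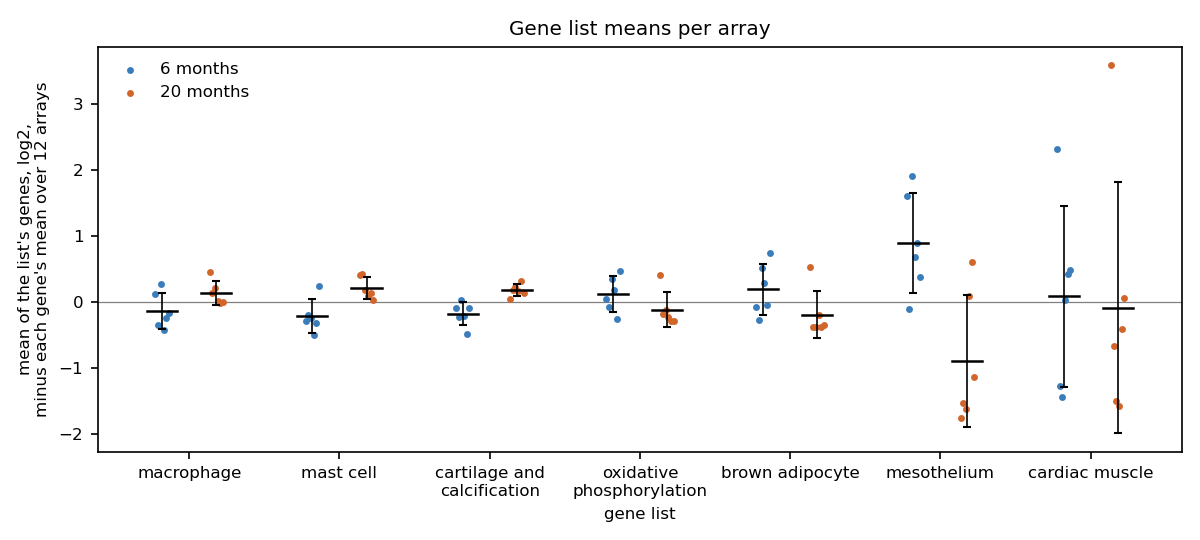
Mean of a list's genes per array, in log2 and relative to each gene's mean over the 12 arrays (vertical axis), for 7 lists (horizontal axis) at 6 months and 20 months; points are mice (6 per age), bars are means and error bars SD. The 20 months heart muscle point at 3.59 is replicate 1, and the mesothelial means reach from -1.77 to 1.91.

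Heat shock and chaperone genes rose as a list (median 0.11 over 19 members, adjusted p = 0.00377, and adjusted p = 0.569 with an estimated correlation). Their examples were Hsph1 (0.45 ± 0.15), Stip1 (0.20 ± 0.07), Hspa8 (0.18 ± 0.07) and Hspb1 (0.26 ± 0.13). TGF-beta and BMP genes rose as a list (median 0.04 over 46 members, adjusted p = 0.00703, and adjusted p = 0.72 with an estimated correlation), with 28 positive and 18 negative changes. Adjusted over the list alone 1 rose, the growth factor gene Gdf10 (0.63 ± 0.13), and 1 fell, the coreceptor gene Tgfbr3 (-0.26 ± 0.06), while Tgfb1 (0.31 ± 0.09) and Ccn2 (0.61 ± 0.20) did not pass. Over all genes Gdf10 passed under 5 alternatives, with array weights, with the value table, with the slide as a fixed or random block and without 6 months replicate 6. Immediate early genes rose as a list (median 0.14 over 22 members, adjusted p = 0.0104, and adjusted p = 0.72 with an estimated correlation). Their examples were Ier3 (0.50 ± 0.19), Egr2 (0.48 ± 0.26), Junb (0.50 ± 0.29) and Jun (-0.53 ± 0.26), and the list's median was -0.25 on slide 1 and 0.55 on slide 3. Cytokine, chemokine and adhesion genes rose as a list (median 0.13 over 24 members, adjusted p = 0.0104, and adjusted p = 0.72 with an estimated correlation). Vcam1 changed by 0.29 ± 0.10, Nfkb2 by 0.18 ± 0.07, Icam1 by 0.26 ± 0.10 and the B cell chemokine Cxcl13 by -1.22 ± 0.49, none past the threshold. Calcium and ion channel genes rose as a list (median 0.04 over 27 members, adjusted p = 0.0237, and adjusted p = 0.72 with an estimated correlation). The values were 0.64 ± 0.17 for Cacna1h, 0.31 ± 0.11 for Trpv4, 0.16 ± 0.06 for Orai1 and -0.27 ± 0.13 for Slc8a1. In all of these lists 0 members passed over all genes, and, apart from the TGF-beta list, 0 adjusted over the list alone.

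The cartilage, macrophage, mast cell, erythroid, oxidative phosphorylation and heat shock calls held under all 25 alternatives run with the preset correlation, and the mesothelial call under all 24 in which it was tested. At that correlation a median of 12 lists also passed when the arrays were split in other ways. Calls that held under these alternatives therefore do not exclude chance. The TGF-beta call was lost without 6 months replicate 6 (adjusted p = 0.0932). Immediate early genes lost theirs without 6 months replicates 1 and 6 and 20 months replicates 2 and 3 (adjusted p up to 0.218). The cytokine call held under 20 of 25, being lost with no filter on dim probes, without 6 months replicates 2 and 4, without the 3 arrays with markers of other tissues and without the 2 arrays with the most probes above background (up to 0.236). The calcium channel call held under 18, being lost with the mean over a gene's probes, without the same 2 arrays and without any 1 of 6 months replicates 3 and 6 and 20 months replicates 4, 5 and 6 (up to 0.19). In all, 10 lists rose and 4 fell with the preset correlation, and 0 passed with an estimated correlation. Without the 3 arrays with markers of other tissues 12 rose and 6 fell. Without 6 months replicate 6 the count of lists that rose was 6, and without 20 months replicate 1 the count that fell was 7.

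The remaining lists did not pass in the main comparison. Under the 25 alternatives with the preset correlation, fatty acid oxidation passed 11 times, white adipocyte 9, collagens 6 and smooth muscle 4, in their main direction. Others passed at most 3 times in theirs. T and NK cell and heart muscle each passed 1 time, against their main direction. Renin-angiotensin genes had a median of -0.06 over 15 members, although their mean was 0.02 and camera placed the list upwards (adjusted p = 0.488). Adjusted over the list alone the converting enzyme gene Ace (0.44 ± 0.12) and the peptidase gene Thop1 (0.26 ± 0.08) rose, and over all genes 0 members did. The angiotensin receptor gene Agtr1b (0.68 ± 0.23) and Ctsa (-0.20 ± 0.10) did not pass. Glutathione and xenobiotic genes had a median of 0.02 over 44 members (adjusted p = 0.133), with 0 members past the threshold over all genes or adjusted over the list alone. Gss changed by 0.26 ± 0.09, Gstk1 by -0.20 ± 0.08 and Ephx1 by 0.20 ± 0.09. Of the genes always given, Cdkn2a and Ucp1 stand with their lists above, and the other 8 did not pass, with changes of 0.14 ± 0.17 for the elastin gene Eln, -0.01 ± 0.08 and -0.03 ± 0.16 for the smooth muscle genes Acta2 and Myh11, -0.04 ± 0.16 for the endothelial nitric oxide synthase gene Nos3, -0.10 ± 0.13 and -0.28 ± 0.10 for Col1a1 and Col3a1, -0.16 ± 0.14 for the fat cell gene Adipoq and -0.02 ± 0.22 for the leukocyte gene Ptprc. The signs for Acta2, Myh11 and Ptprc changed with the scaling.

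Positive medians were found for circadian clock (0.10, adjusted p = 0.172), collagens (0.03, 0.0998), elastic fibre (0.02, 0.122), NADPH oxidase (0.13, 0.0867), nitric oxide and cGMP (0.0005, 0.709), interferon-stimulated genes (0.07, 0.133), MHC class II (0.09, 0.122), MHC class I (0.05, 0.416), complement (0.05, 0.122), endoplasmic reticulum stress (0.02, 0.488), smooth muscle (0.04, 0.172), adventitial fibroblast (0.05, 0.427), B and plasma cell (0.14, 0.293) and skeletal muscle (0.03, 0.791). Negative medians were found for antioxidant defence (-0.06, adjusted p = 0.756), fatty acid oxidation (-0.21, 0.0533), cholesterol synthesis (-0.14, 0.462), matrix proteases (-0.01, 0.488), vasoactive receptors (-0.04, 0.427), imprinted growth genes (-0.08, 0.507), glucocorticoid response (-0.05, 0.756), insulin, IGF and sirtuin signalling (-0.12, 0.427), Hox genes (-0.08, 0.48), endothelium (-0.09, 0.489), T and NK cell (-0.18, 0.871), white adipocyte (-0.16, 0.0825), heart muscle (-0.30, 0.871) and Schwann cell and nerve (-0.08, 0.488). The 4 measured genes of lymphatic endothelium were too few for the test and had a median of 0.15. Over all genes 1 member of these lists rose, Igfbp2 of the insulin list. Adjusted over the list alone 1 member each rose in the elastic fibre (Efemp1, 0.43), interferon (Mx2, 0.60), T and NK cell (Cxcr6, 0.40) and insulin (Igfbp2) lists, and 0 in the others. Camera's direction was upwards against a negative median for the matrix protease, vasoactive, glucocorticoid and heart muscle lists, which also had negative means. It was downwards for skeletal muscle, whose mean was -0.10, and upwards for nitric oxide, whose mean was -0.002.

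The spread between mice was also compared, to ask whether old animals varied more. The median log2 ratio of the variance at 20 months to that at 6 months was -0.51 (two-sided permutation test, p = 0.22), so that a difference in spread was not shown. Without 20 months replicate 1, the array with the highest heart muscle markers, it was -1.0 (permutation p = 0.02).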

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

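The 2 tests with a marker covariate were fixed before their results were seen, but the pattern they address was picked after the list means per array had been seen. A value was singled out where 1 mouse of an age lay far from the other 5, by Dixon's ratio at its 95% critical value, which chance passes in about 1 of 20 groups. Of 264 groups (array measures, list means and named genes at each age) 26 were singled out, where chance gives 13.2. Of these, 12 concern 20 months replicate 1 and 6 concern 6 months replicate 4.

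In 20 months replicate 1 the heart muscle mean was 3.59 (others -1.58 to 0.06), the skeletal muscle mean 0.54 (others -0.38 to -0.04), the brown adipocyte mean 0.52 (others -0.38 to -0.20), the oxidative phosphorylation mean 0.40 (others -0.29 to -0.12), the Schwann cell and nerve mean 0.21 (others -0.13 to -0.03) and the TGF-beta mean -0.13 (others 0.04 to 0.12), all relative to the 12-array mean of the same genes. Among single genes its log2 signal was 3.05 for Elovl3 (others -0.89 to -0.08), 7.48 for Cox6c, 7.13 for Atp5g2 and 7.83 for Atp5e, all above the other 5 mice, and 2.61 for Gdf10 and 1.89 for Fmod, both below them.

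In 6 months replicate 4 the probes well above background made up 55.8% (others 48.9% to 50.2%), the cell cycle mean was 0.77 (others -0.12 to 0.06), and the log2 signals were -0.30 for Cdt1 and -1.28 for Plk1, above the others, and -2.42 for Icam1 and 1.13 for Folr2, below them. In 20 months replicate 5 the probes well above background made up 55.5% (others 47.5% to 49.99%). In 20 months replicate 3 the insulin, IGF and sirtuin mean was 0.10 (others -0.06 to 0.005) and Slc8a1 stood at -3.17, below the others. Adcy1 stood at -3.12 in 6 months replicate 3, below the others, Hapln1 at -1.11 in 6 months replicate 1, above them, and Thop1 at -0.11 in 20 months replicate 2, above them. Cma1 stood at -0.14 in 6 months replicate 6, above the others, and Hbb-b2 stood at 3.53 in 6 months replicate 5, above the others.

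Outside the genes compared, 16 of 6373 probes without a gene name passed the threshold, 15 higher and 1 lower at 20 months. Of these, 11 lay on the segment of chromosome 1 and the unplaced sequence described in the results, and 3 on chromosome 12, with rises of 1.14, 1.05 and 0.51.

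The fall of the oxidative phosphorylation list went along with the brown adipocyte markers, which were highest in the same arrays, with Ucp1 at 7.74 ± 0.65 at 6 months (SD, n = 6), although the labels state that fat around the vessel was removed. With the mean of the 13 brown adipocyte markers as a covariate, the list's median change went from -0.24 to 0.0074. Its mean change went from -0.24 (SE 0.15) to 0.02 (SE 0.07, 95% interval -0.15 to 0.18). A share of brown fat that differed between the dissected aortas would give such a result. None of the markers is in the other list, but they include the cytochrome c oxidase genes Cox7a1 and Cox8b. Deviations of the lists within the ages correlated at 0.92. Part of the shrinkage may thus be built into the covariate. With the 11 heart muscle markers as a covariate the median went from -0.24 to -0.23 (95% interval of the mean -0.56 to 0.11). This covariate thus took up little of the fall, but the interval is too wide to exclude heart muscle as a part of the cause. Age stays open as well, since the tests cannot tell whether brown fat around the vessel changed with age, differed by dissection, or fell together with oxidative genes in the vessel wall.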

How the results depend on the processing

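The settings without 3 and without 2 arrays were chosen after seeing the data, and all others before. All 20 named genes past the threshold kept their direction in every setting, 378 times past the threshold and 220 times not. Their values separated the ages completely, so leaving out arrays, single slides, blocks or array weights could not reverse them. In those settings the kept direction is no further support. The other 67 named genes kept their direction except 40 times, never past the threshold. Signal over background limits the counts, since the tested genes and their adjustment change with the filter. Where no cause follows from the construction, the cause was not tested.

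For genes higher and lower at 20 months (45 and 9) and at 1.5-fold or more (35 and 6), normexp gave 5 lower, and 22 and 1 at 1.5-fold. Median scaling gave 29 and 2 (93.5% higher, against 83.3%), and 2 lower at 1.5-fold. No filter gave 20 and 3, the same at 1.5-fold, over more genes. The slide as a random block gave 68 higher. Array weights gave 101 and 23, and 68 and 11 at 1.5-fold. With the replicate number as a block, 7 and 0 passed, the same at 1.5-fold. Across genes, arrays of the same number correlated at -0.36 to 0.32 after removing the age means, and 2 of 12 arrays correlated best with their own number. No pairing of the mice by number was thus visible in the values, which does not exclude a pairing in the design. Each slide alone, with fewer arrays, gave 0 and 1, 1 and 0, and 0 and 0, the same at 1.5-fold. Without 3 arrays 26 and 4 passed, and without 2 arrays 15 and 0, the same at 1.5-fold, from fewer samples. Leaving out 1 array gave 18 to 51 higher and 2 to 12 lower, and 17 to 44 and 2 to 7 at 1.5-fold. The 54 genes shared 49 with the 66 of the slide block and 28 with the 31 of median scaling. Between slides 268 genes differed.

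Gene lists higher and lower were 10 and 4. With an estimated correlation 0 and 0 passed, and by fry 2 and 0. Lists lower were 7 on slide 3 alone and 2 without 2 arrays. Leaving out 1 array gave 6 to 14 higher and 3 to 7 lower. The spread of -0.51 (permutation p = 0.22) was -1.02 (permutation p = 0.02) without 3 arrays and -1.0 to -0.21 leaving out 1 array.

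Of genes that did not pass, these changed sign. Acta2 was 0.0026 with normexp, 0.022 with quantile normalization, 0.027 with median scaling, 0.038 in the value table, 0.025 and 0.013 on slides 1 and 3, 0.084 without 3 and 0.012 without 2 arrays, and -0.040 to 0.024 leaving out 1 array. Myh11 was 0.071 with quantile normalization, 0.0041 with median scaling, 0.065 in the value table, 0.26 on slide 3, 0.058 without 3 and 0.0072 without 2 arrays, and -0.18 to 0.035 leaving out 1. Ptprc was 0.014 with median scaling, 0.31 on slide 1, 0.0145 without 3 and 0.24 without 2 arrays, and -0.15 to 0.12 leaving out 1. Nos3 was 0.056 and 0.13 on slides 1 and 2, and -0.12 to 0.090 leaving out 1. Col1a1 was 0.053 on slide 2 and 0.015 without 3 arrays. On slide 1 Vcam1 was -0.062, Ier3 -0.053 and Elovl3 0.44, and on slide 2 Hbb-bt was -0.011.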

Other observations

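The segment of chromosome 1 and the unplaced sequence, the test on Sp100, Sp110 and Sp140 and the genes of the next paragraph were chosen after their values were seen, and the counts of other splits, the column test and the test of correlated copies were fixed before their results were seen.

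Among the changed genes that the rule did not name, 5 encode secreted growth factors. Angpt4 rose by 0.95 ± 0.13 (SE; its 3 probes by 0.0047 to 0.95), Pgf by 0.85 ± 0.15, the midkine gene Mdk by 0.63 ± 0.12, Vegfd by 0.62 ± 0.12 and Fgf7 by 0.45 ± 0.08, with adjusted p of 0.0113, 0.0327, 0.0453, 0.0453 and 0.0448. The lymphatic vessel gene Ccbe1 rose by 0.55 ± 0.10 (its 3 probes by 0.16 to 0.55) and the macrophage gene Gpnmb by 0.53 ± 0.09. The calcium channel subunit Cacna2d3 (0.99 ± 0.14), the neuroglobin gene Ngb (0.96 ± 0.15, above background on 1 of 6 arrays at 6 months, so that the size is uncertain) and the kinesin Kif1a (0.74 ± 0.11) rose as well. No list of these 10 genes was tested. All 10 rose on each slide alone, and their values under the other alternatives are not given here. By fry's test for changes in either direction, 4 lists passed: senescence and cartilage (adjusted p = 3.6e-05 each), TGF-beta (0.0361) and insulin, IGF and sirtuin signalling (0.0361), none of which it compares with other genes.

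For the genes past the threshold, 2 of 100 splits of the 12 arrays, the real one included, gave as many (54 in the real split, 1178 in the highest other). Likewise 2 of 100 did at 1.5-fold or more (41 against 324). Such a count is thus unlikely by chance but not excluded, since another split gave far more. The 100 splits were drawn from 462 and did not keep the slides balanced. The highest other split parted arrays with high from arrays with low oxidative phosphorylation means, but for 20 months replicate 3, which points to a structure of the samples. For the lists chance is not excluded, since 38 of 100 splits gave as many (14 in the real split, a median of 12 and at most 25 in the others). An even gradient across slide columns would place the 6 months array of column 4 at the level of the 20 months arrays, at a relative position of 1 or more, whereas over 63 genes called without it its median position was 0.24 (quartiles -0.07 and 0.70), which argues against such a gradient. An effect of column 3 alone cannot be told apart from age, which stays open.

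The 6 genes on chromosome 1 and unplaced sequence are not shown to lie together. Their rise may come from near-identical copies that several probes measure, or from an interferon response of the Sp100 family. Csprs is a component of a repeated Sp100-related sequence and is not shown to be a member of that family. On the second, the mean change of Sp100, Sp110 and Sp140 was 0.014 (95% interval -0.13 to 0.16), and 0.11 (-0.0061 to 0.23) over all their 7 probes. These genes thus showed no shared rise of 0.5 or more, the size asked of such a response. That limit was set after their values were seen, so it is no independent test. A single Sp140 probe rose by 0.55 ± 0.13, and an unnamed probe at 87351659 on chromosome 1 by 1.91 ± 0.25. Neither was tested further. The first stays open: over the 15 pairs of the 6 changed genes the mean correlation of deviations within the ages was 0.18 (-0.52 to 0.88 between pairs), where a shared signal asks for more than 0.5 and separate signals for less than 0.1. A difference in copy number of these genes between the mice and a change with age were not tested and stay open too.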
